A study of Rattus norvegicus with 6 samples.

How the data were processed

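RNA was measured in bone marrow-derived macrophages, which are grown in culture from marrow precursors, of Wistar-Kyoto (WKY) rats. Per the labels, 3 libraries came from wild-type rats and 3 from rats carrying a knockout of Cyp2j4, a cytochrome P450 gene. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase on a column, selected with poly-T beads and made into libraries with the TruSeq RNA kit. The protocols also mention mouse and human macrophages, which were not analysed here.

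The authors deposited 1 table of raw counts of reads per gene, not normalized, with 1 column per library. Per the submitters' processing notes, reads were aligned to the rat genome build rn4 with TopHat2 and counted with HTSeq. Versions, the annotation release, the strand setting and the rule for overlapping genes are not given in the sources used here. Reads listed as ambiguous between genes (0.799% to 0.943% per library) were not counted for any gene. Other reads of antisense or overlapping genes may be counted for either partner. The table held 29516 Ensembl gene IDs and 5 HTSeq summary lines, which name no gene and were kept out of library sizes and tests. Each column name matched the description of 1 sample, and 0 columns belonged to other samples.

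The deposited table does not pair its Ensembl IDs with gene names, and 0 of the 29516 IDs matched the RefSeq gene table used here, which covers assembly GRCr8 and lists no Ensembl IDs. No gene was therefore named from its ID. The expression of Cyp2j4 itself, the level of the other epoxygenases, and the 18 gene lists and 11 marker lists planned before the data were examined (such as extracellular matrix, PPAR-gamma targets and fibroblast markers) were not analysed here, for want of names. For the same reason no check of GC content, gene length or cell type markers was made. No coordinates are given.

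Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 11645 of the 29516 IDs (12381 had 0 counts in every library). Library sizes were scaled by TMM, and knockout was compared with wild type by the quasi-likelihood F test (glmQLFit and glmQLFTest with their default settings), with genotype as the only term. Calls are at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Normalized counts (CPM, scaled to a total of 1000000) use the TMM-scaled library sizes, and log2 CPM used a prior count of 2. Measures of whole libraries were compared with exact two-sided permutation tests, which for 3 libraries against 3 cannot give a p below 0.1. The labels do not state which libraries came from which rats or on which day they were made, so p-values measure the spread between these libraries.

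The rule for genes given individually, set before the data were examined, took the genes with the largest fold change (at a mean log2 CPM of at least 2) and the genes with the highest mean CPM among calls whose groups did not overlap. It passed over genes with no symbol. As no gene has one here, that exception was dropped after the data were seen, and the first gene of each part in each direction is given by its ID.

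The alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), other thresholds, each library left out in turn, and the replicate number as a block. Sample quality weights, bias-adjusted deviances in the quasi-likelihood fit and thinning to the lowest library total were added after seeing the data. The correlation of residuals between same-numbered libraries of both groups was -0.44, -0.14 and 0.15, so the numbers were not treated as pairing the libraries. The highest between any libraries of different groups was 0.445, for wild type replicate 1 and knockout replicate 2. Whether these shared a culture or a processing step is not stated in the labels and was not tested. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of at least 9.85 over genes with at least 20 counts), so no library was taken as a copy of another. The tests were tried on simulated data with the real means, spreads and library sizes of the 11645 genes, 200 of them changed. The quasi-likelihood test recovered 43.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, with 5 false calls among 157. DESeq2 recovered 47.8%, 85.1% and 100%, with 36 false calls among 191. The simulated genes varied independently of one another, and no simulated library was set apart from its group. In the data knockout replicate 2 stood apart, so these rates may not hold there.

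Gene counts per library ranged from 21590429 to 33916549, so that 3 counts correspond to between 0.0885 and 0.139 CPM. Reads were counted without molecular identifiers, and counts that low cover counting error only.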

Results

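The transcriptome of cultured bone marrow-derived macrophages was compared between wild-type WKY rats (3 libraries) and Cyp2j4 knockout rats of the same strain (3 libraries). Cyp2j4 belongs to the epoxygenases, cytochrome P450 enzymes that convert arachidonic acid to epoxyeicosatrienoic acids. The question, as the series title states it, was whether a macrophage epoxygenase shapes a fibrosis-associated expression pattern. The genes are identified in the counts by Ensembl IDs alone, so the targeted gene and matrix genes were not analysed here by name, and the genotype labels were not checked against the expression of Cyp2j4.

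Wild-type libraries held 33257723, 27248491 and 33916549 gene counts in replicates 1 to 3, and knockout libraries 21590429, 23923666 and 22034218. Every knockout library was shallower than every wild-type library (n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows; 0.233 after Benjamini-Hochberg adjustment over 7 measures of the libraries). Reads that fell on genes made up 80.6% ± 0.173 of the reads listed in wild type and 81.0% ± 0.301 in knockout (SD, n = 3; exact permutation p = 0.1, adjusted p = 0.233). Reads outside annotated genes made up 10.6% ± 0.184 in wild type and 10.1% ± 0.511 in knockout (SD, n = 3; exact permutation p = 0.2, adjusted p = 0.233). The 10 most abundant genes took 19.7% ± 1.13 of the gene counts in wild type and 21.4% ± 1.48 in knockout (SD, n = 3; exact permutation p = 0.2, adjusted p = 0.233). The numbers of genes with at least 10 counts were 11811, 11656 and 11831 in wild type and 11537, 11486 and 11629 in knockout.

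Wild-type libraries resembled one another closely, while knockout replicate 2 stood apart from both other knockout libraries. Across genes, Spearman correlations of log2 CPM were 0.996 to 0.997 among the wild-type libraries and 0.994 between knockout replicates 1 and 3. Knockout replicate 2 correlated at 0.983 with knockout replicate 1 and at 0.985 with knockout replicate 3. With wild type replicates 1, 2 and 3 it correlated at 0.993, 0.985 and 0.986. Knockout replicate 1 correlated with wild type replicate 3 (0.995) about as closely as with knockout replicate 3. The first principal component, 41.7% of the variance, placed knockout replicates 1 and 3 at 21.1 and 29.6 and the wild-type libraries between -17.8 and -11.0. Knockout replicate 2 lay at -5.12 on it, between those groups, and at 34.8 on the second component (34.5% of the variance), where the other 5 libraries lay between -14.1 and 2.0.

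**Figure D1:**
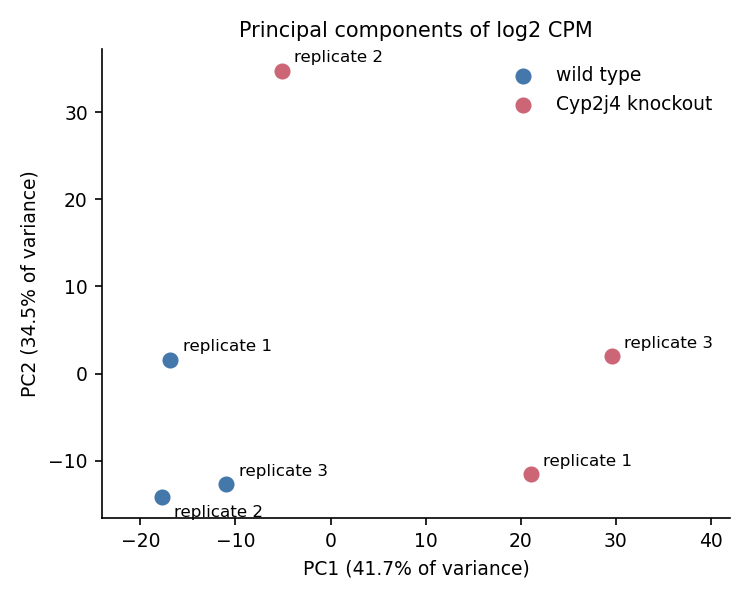
First against second principal component of log2 CPM for the 6 libraries, with wild type in blue and Cyp2j4 knockout in red. Knockout replicate 2 lies at 34.8 on the second component, and the highest of the other libraries lies at 2.0.

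In knockout macrophages, 13 genes rose and 1 fell. The gene that fell dropped from a mean of 33.4 CPM to 1.36 CPM, and the genes that rose included one of 143 CPM in knockout cells and a group of 7 with less than 1 CPM in wild type. All 13 rose by more than 2-fold, with a smallest fold of 2.52 and a median fitted fold of 4.95 (edgeR quasi-likelihood test, 11645 genes, adjusted p from 0.0105 to 0.0345). In each of the 14 genes the 3 knockout libraries lay entirely on one side of the 3 wild-type libraries. Of the genes tested, 15.0% were separated in this way, 878 of them higher and 867 lower in knockout, where chance gives 10%. At an unadjusted p under 0.05 there were 891 genes, of which 549 were higher and 342 lower in knockout, against 582 expected by chance. Other splits of the 6 libraries gave from 77 to 1279 such genes, so the excess over 582 is not by itself a sign of a genotype effect.

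ENSRNOG00000031004 fell by 4.61 ± 0.26 on the log2 scale (SE, n = 3 per group; edgeR quasi-likelihood adjusted p = 0.00258), so that wild type exceeded knockout 24.5-fold. It had 992, 1067 and 1123 counts in the wild-type libraries and 15, 38 and 37 in the knockout libraries, with means of 33.4 ± 3.72 CPM and 1.36 ± 0.588 CPM (SD, n = 3). Knockout replicates 1, 2 and 3 stood at 0.679, 1.69 and 1.71 CPM, and the lowest wild-type library at 30.3 CPM.

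ENSRNOG00000010918 was the most abundant gene that rose. Its level was 50.2 ± 7.32 CPM in wild type and 143 ± 12.8 CPM in knockout (SD, n = 3), a 2.86-fold rise (log2 fold change 1.51 ± 0.12 SE, edgeR quasi-likelihood adjusted p = 0.0105). ENSRNOG00000019987 showed the largest rise among the called genes of at least 2 mean log2 CPM. It went from 7.66 ± 2.08 CPM to 38.0 ± 5.64 CPM (SD, n = 3), a 4.95-fold rise (log2 fold change 2.31 ± 0.20 SE, edgeR quasi-likelihood adjusted p = 0.0105). Neither rise passed the threshold in the fits without wild type replicate 2, wild type replicate 3 or knockout replicate 3, where the edgeR adjusted p lay between 0.0514 and 0.128 and the log2 fold changes stayed between 1.41 and 1.53 for ENSRNOG00000010918 and between 2.19 and 2.37 for ENSRNOG00000019987.

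**Figure D2:**
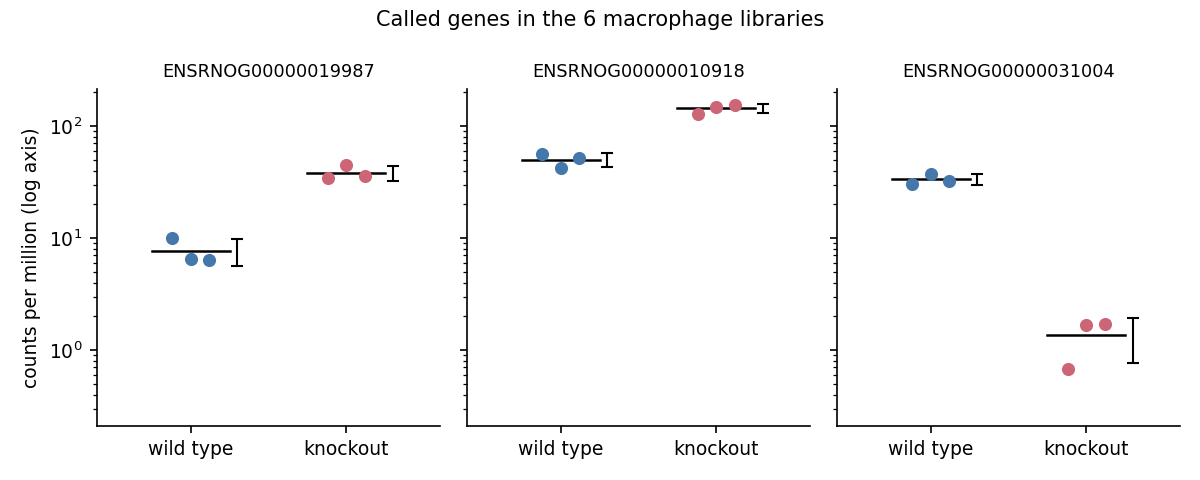
CPM (log axis) of 3 called genes in the wild-type (blue) and Cyp2j4 knockout (red) libraries, 1 point per library, with the mean as a line and the SD as the bar beside it. ENSRNOG00000019987 and ENSRNOG00000010918 were higher in all 3 knockout libraries and ENSRNOG00000031004 was lower in all 3.

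The 7 genes under 1 CPM in wild type had wild-type means from 0.0102 to 0.970 CPM, 6 of them under 0.5 CPM, and knockout means from 0.938 to 4.29 CPM. Summed over the 3 wild-type libraries they had from 1 to 93 counts each, and summed over the 3 knockout libraries from 62 to 284 counts, although the knockout libraries were the shallower. In every knockout library each of the 7 had at least 17 counts. A further 5 genes that rose lay between 1 and 10 CPM in wild type, and 1 lay above 10 CPM.

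Differences of more than 2-fold were found mostly among genes of low abundance, and there mostly as higher values in knockout. Among the 909 genes under 1 mean CPM, 56 were more than 2-fold higher and 8 more than 2-fold lower at an unadjusted p under 0.05, and among the 3076 genes of 1 to 10 CPM these numbers were 82 and 14. Among the 6006 genes of 10 to 100 CPM they were 11 and 2, and among the 1654 genes over 100 CPM they were 2 and 1. The knockout libraries were not alike at weakly expressed genes. Over 89 genes called more than 8-fold higher without knockout replicate 2, medians were 1.17, 0.400 and 2.47 CPM in knockout replicates 1 to 3. Choosing genes without replicate 2 favours a lower value in it. None of the genes over 100 mean CPM over the 6 libraries was called at an adjusted p under 0.05 (edgeR quasi-likelihood), while 111 of them had an unadjusted p under 0.05, 81 higher and 30 lower in knockout. Of the same 1654 genes, DESeq2 called 11 and limma-voom 0.

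**Figure D3:**
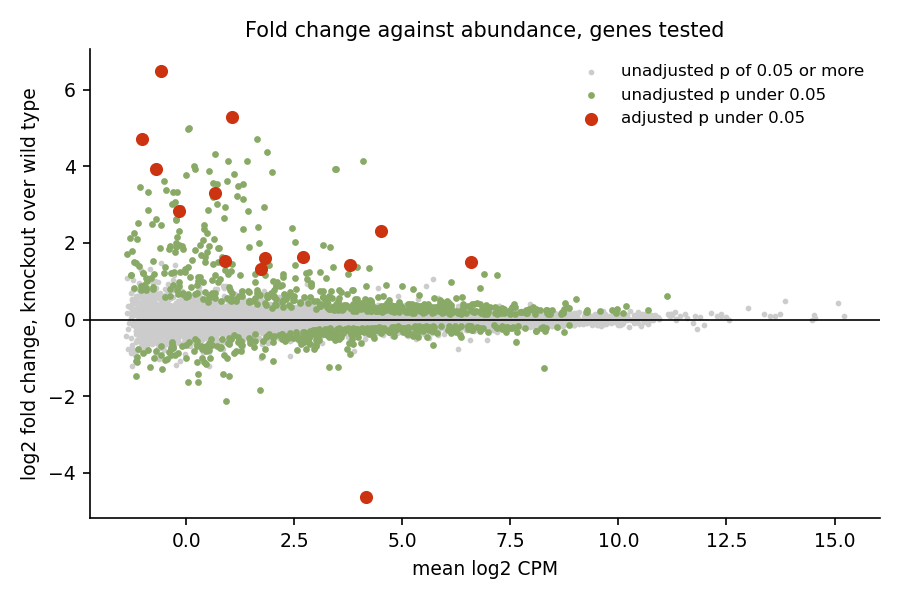
Log2 fold change of knockout over wild type against mean log2 CPM for the 11645 genes tested, in grey where the unadjusted p was 0.05 or more, green where it was under 0.05 and red where the adjusted p was under 0.05. The 13 called genes above 0 and the 1 below it are the red points, and the green points of large fold lie mostly above 0 at low abundance.

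The number of genes called depended on which libraries, which genes and which test were used. Without knockout replicate 2 the edgeR test called 207 higher and 43 lower genes, which included the 14 called with all libraries. The 1 lower gene was called whichever library was left out. The number of higher genes was 3, 0 and 0 without wild type replicates 1, 2 and 3, 5 without knockout replicate 1 and 1 without knockout replicate 3, and these fits had between 535 and 1245 genes at an unadjusted p under 0.05. The same fits with DESeq2 or limma-voom were not run. With all libraries DESeq2 called 178 higher and 18 lower genes and limma-voom 13 and 1, and both sets included the 14. DESeq2 gave an adjusted p to 16489 genes in place of 11645, and 161 of its 196 calls were among the latter. With no filter on low counts (17135 genes) the edgeR test called 54 higher and 5 lower genes.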

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

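The sample quality weights, bias-adjusted deviances and thinning were chosen after seeing the data; all other alternatives were set before. ENSRNOG00000031004 stayed past the threshold under all 18 alternatives (log2 fold change -4.87 to -4.29, highest adjusted p 0.0402), and the 2 higher genes given by ID under 15 of 18 each. The 13 higher genes became 54 with no filter on low counts (and the 1 lower gene 5), 178 and 18 with DESeq2, 121 and 18 under limma-voom with sample quality weights, where knockout replicate 2 had a weight of 0.192 and no other library under 1.12, and 0 higher genes at an adjusted p under 0.01 with edgeR (891 genes at an unadjusted p under 0.05; DESeq2 called 117 higher genes and limma-voom 4 at that threshold). Scaling, the 1 CPM filter, limma-voom, the fold thresholds and bias-adjusted deviances gave 10 to 14 higher genes and the 1 lower gene, and thinning to the lowest total gave 9 and 1. With the replicate block the count was 26 higher and 1 lower, of which 8 and 1 were shared with the calls without it. The numbers were not treated as pairing the libraries, and whether they do is not known. Leaving out 1 library gave from 0 to 207 higher and from 1 to 43 lower genes. The counts were 0 without wild type replicate 2 or 3, 1 without knockout replicate 3, 3 without wild type replicate 1, 5 without knockout replicate 1 and 207 without knockout replicate 2. With 5 libraries the fit has fewer residual degrees of freedom, and the cause of the low counts was not tested further. The median log2 fold change of all genes lay between -0.06 and -0.01 under the 4 scalings. The planned tests of gene lists, marker lists and epoxygenase levels, with their alternatives, were not run because no gene names were given. At these depths 3 counts are 0.0885 to 0.139 CPM, which limits what can be said of genes below that level.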

Other observations

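The thinning, the tests of scaling, of low depth, of a wrong label, of admixed wild-type RNA and of the called genes in knockout replicate 2, the choice of genes by fold alone and the counts of edgeR calls over other splits were chosen after the data were seen. The bounds for the thinning and for the tests not named here were written before their values, for patterns already seen. Without knockout replicate 2, 89 genes were more than 8-fold higher in the other knockout libraries than in wild type, and 2 were more than 8-fold lower (edgeR quasi-likelihood, adjusted p under 0.05). The 89 higher genes had median levels in wild type of 0.0918, 0.0705 and 0.144 CPM in replicates 1 to 3, and the highest wild-type mean among them was 1.79 CPM. Their medians were 1.17 CPM in knockout replicate 1, 0.400 in knockout replicate 2 and 2.47 in knockout replicate 3. Together they made up 0.0222%, 0.00777% and 0.0433% of all counts in those libraries and 0.00181% in wild type on average. In knockout replicate 2, 81 of the 89 lay above all 3 wild-type libraries and 87 below both other knockout libraries, and choosing genes for high values in those other libraries favours the second of these counts.

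Over the 250 genes called without knockout replicate 2, its median position was 42.7% of the way from the wild-type to the knockout mean on the log2 scale, and 44.0% of the genes lay nearer to the knockout mean. By the first bound written for a wrong label, at most 50% nearer to knockout, that share would have counted for one, and the bound was replaced after it was seen because it left no room for a library between the groups. A wild-type library under a wrong label is argued against by the 79.6% of these genes at which it lay beyond all 3 wild-type libraries on the knockout side. Choosing genes by those same 3 wild-type libraries favours this outcome, to an extent that was not measured. Wild-type RNA mixed into it is argued against by its level of ENSRNOG00000031004, which allows 1.57% over the mean of the other knockout libraries and 5.05% with no baseline. That rests on 1 gene, which was chosen with this library in the fit but was also called without it. Low depth is argued against by its total, which ranks 3 of 3 from the lowest among the knockout libraries, and noise of weakly expressed genes by its highest correlation with another knockout library of 0.932 over genes of at least 100 CPM, against 0.979 between the other knockout libraries. For the 89 genes, a second source of transcripts, such as a trace of other cells at differing shares in the knockout libraries, stays open. So does a knockout response of differing strength between cultures. The log2 ratio of its CPM to the other knockout libraries over the 89 genes had an interquartile range of 0.925, under the bound of 1 set beforehand. But choosing genes by fold alone gave 1.03 over 36 genes (median ratio -2.27, against -0.39 over 6 and 1.52 over 5 genes with knockout replicates 1 and 3 left out in its place). Neither was tested for the departure of knockout replicate 2 over genes of at least 100 CPM. A weaker response as the whole cause is argued against by the second principal component. Knockout replicate 2 lay at 34.8 on it, and the other libraries of both genotypes between -14.1 and 2.0.

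Most called genes were higher in knockout: after thinning to the lowest library total 90.0% of calls were, and without knockout replicate 2 82.8% were, both above a bound of 80% written before these values, which argues against a difference in library totals and that library as the whole cause, and scaling is argued against by the other scalings, which shifted the median log2 fold change by at most 0.0491, against at least 1.33 for each higher call. Leaving out other libraries or tightening the threshold left few calls, with 3 of 4 higher without wild type replicate 1, 0 of 1 without wild type replicate 2 or 3 or at an adjusted p under 0.01, 5 of 6 without knockout replicate 1 and 1 of 2 without knockout replicate 3. Of the 10 splits of the 6 libraries, 1 gave at least 13 calls in one direction and 1 gave at least 1, in both cases the real split, and the highest other split gave 0. With 10 splits a share under 0.05 cannot be reached. In 3 other splits more genes had an unadjusted edgeR p under 0.05 (1006, 1066 and 1279 against 891). Each of them set wild type replicate 1 with knockout replicate 2 (the fourth such split had 181). Every other split holds both genotypes on each side in the same unequal numbers, so a genotype effect can enter its count. The splits that kept wild type replicate 1 and knockout replicate 2 apart had from 77 to 210. A genotype effect equal in all libraries does not by itself account for that contrast, which points to a further structure of the libraries. An effect of differing strength between libraries was not tested. The genotype stays open, untested, and so does a second source at a lower share in knockout replicate 2: the median log2 ratio of its CPM to the other knockout libraries over the 13 genes was 0.050, but calling them with all libraries favours a small spread.

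DESeq2 called 196 genes where the quasi-likelihood test called 14. DESeq2 tested more genes, but 161 of the 196 were in the edgeR fit, so the added genes account for only part of the difference. With no filter edgeR called 59 genes. The split that set wild type replicate 1 with knockout replicates 2 and 3 against the other 3 libraries gave 127 DESeq2 calls, over 50% of the real count, and 0 edgeR and limma-voom calls, while 1 further split gave 30 DESeq2 calls and the remaining 7 gave 0. Each of these other splits holds both genotypes on each side in the same unequal numbers, so a genotype effect can enter its calls. An effect equal in all libraries does not by itself account for 127 and 30 calls beside 0 in the rest. Both of those splits set wild type replicate 1 with knockout replicate 2, as did others that gave 0. Their calls point to a structure of the samples apart from an equal genotype effect. Whether it entered the 196 calls of the real split cannot be told from the splits. In the self-test DESeq2 gave 36 false calls among 191. Its simulated libraries held no such structure, but their spreads were taken from the real libraries, knockout replicate 2 included. The self-test therefore cannot tell how many false calls would arise without that structure.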
